A study of Mus musculus with 8 samples.

How the data were processed

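Single-nucleus RNA sequencing was performed on striatum of mouse pups at postnatal day 8, in 8 libraries of 1 mouse each. The 4 control mice carried the Dlx5/6-Cre transgene alone and the 4 conditional knockout mice carried Dlx5/6-Cre with 2 conditional Zswim6 alleles. Dlx5/6-Cre drives recombination in the forebrain GABAergic lineage, which includes the striatal spiny projection neurons (SPNs). Per the labels' protocols, mice of both sexes were used, the striatum was dissected from vibratome slices and frozen, nuclei were captured without sorting on a 10x Genomics Chromium controller with a 3' gene expression kit, and the sequencing core aligned the reads. Cell Ranger 6.1.2 and the genome build GRCm38 are named in the submitters' processing notes. The authors deposited, for each mouse, a matrix of raw UMI counts per gene and barcode, with whole numbers and no normalization. Whether introns were counted, which annotation was used and which exons of Zswim6 are removed by Cre are not given in the sources used here. The sequencing core's sample numbers fall into 2 series, one with control replicate 1 and conditional knockout replicate 3 (the 2-mouse series) and one with the other 6 mice (the 6-mouse series). The series was treated as a batch.

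The deposited matrices held 57193 barcodes and 32285 genes, with 21131716 to 53135404 UMIs per library. Nuclei with fewer than 500 detected genes (1157 barcodes) or over 5% mitochondrial UMIs (60 barcodes) were left out, which kept 55976. Scrublet's automatic threshold marked 5 nuclei in all, so doublets were instead taken as the nuclei with the highest scores in each library, at 0.8% per 1000 barcodes. This removed 3306 nuclei and left 52670. Nuclei were clustered with scanpy 1.11.5 (3000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 1.0), giving 31 clusters. Clusters were named only from cell type markers fixed before the data were examined, with at least 3 detected markers. The files hold no cell type annotation by the authors that was used here, so the names are rebuilt and are given as "like". Clusters in which markers of another class stood beside SPN markers at 0.6 or more of the SPN level were kept out of every class as mixed nuclei (15.1% of nuclei), a threshold set after the clusters had been seen. Clusters with too few markers, or with low UMIs and no marker among their leading genes, stayed unnamed (4.43% of nuclei).

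Counts were summed per mouse and class, since nuclei of 1 mouse are not replicates. A mouse with fewer than 20 nuclei of a class was left out of that class. The sums were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr defaults), with Benjamini-Hochberg adjustment within each class and a threshold of 0.05. The difference in genotype effect between direct-pathway and indirect-pathway SPN-like nuclei was tested as an interaction on both sums of each mouse, with the mouse as a block. Levels per mouse are log2 CPM (counts scaled by library size) with a prior count of 2. Gene groups were tested with camera in limma 3.58.1 with a preset correlation of 0.01, over lists with at least 5 tested genes, beside camera with an estimated correlation and fry. The 28 gene lists and 16 cell type marker lists were fixed before the data were examined. Shares of nuclei and other single values per mouse were compared with exact permutation tests, always two-sided, whose smallest possible p is 0.0286 for 4 mice against 4 and 0.1 for 3 against 3. Gene positions came from the GENCODE vM21 annotation of GRCm38, which gave a position for 99.85% of the 32285 genes.

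The named genes followed a rule written before the data were examined: Zswim6 always, then for each SPN-like class up to 10 called genes per direction with an average log2 CPM of at least 3 and no overlap between the groups, then called members of the fixed lists, the 10 interaction calls of smallest p and up to 3 calls per other class. For the classes, the rule left gene models without a name, the sex genes Xist, Tsix, Ddx3y, Uty, Kdm5d and Eif2s3y and mitochondrially encoded genes unnamed. Every other gene named was chosen after its value was seen. AC149090.1 and Zfp773 were named because few genes were called, and mt-Nd2, mt-Nd3 and other list members because they were called over their list alone. Uncalled members such as Grin1, Drd2 and Mef2c are examples of a changed list. The rest were calls with the core series as a covariate (Spock1, Oprm1, Ebf1, Rarb, Pde10a and Foxp1, and Cntn5 and Foxp2 within 1 class), and genes of chromosome 13 taken at an unadjusted p.

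The tests were run on simulated data with known changes. In simulated direct-pathway sums, 74% of genes changed 2-fold and 31.2% of genes changed 1.5-fold were recovered, and 7 of 14174 unchanged genes were called. The corresponding values were 85.4%, 29.6% and 14 of 12797 for indirect-pathway sums, and 55.3%, 7% and 13 of 12818 for the interaction. The simulated sums of both classes were drawn independently, without the variation that classes of 1 mouse can share. The interaction values thus do not describe that test on the real sums, where differences in log2 fold change as small as 0.12 were called. Within each SPN-like class, most simulated 1.5-fold changes of single genes were below the threshold with these depths, this spread and 4 mice per genotype. The shares of these in the loss were not separated.

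Alternatives were DESeq2 1.42.0, limma-voom, DESeq2-type size factors, no filter on low counts, the core series as a covariate, the 6-mouse series alone, Xist as a covariate for sex, doublets kept, at least 1000 genes per nucleus, a Leiden resolution of 0.5, equal numbers of nuclei per mouse, and leaving out each mouse in turn. Nuclei under 3 times the median UMI count, UMIs thinned to the same total per mouse, and the core series with Xist as covariates were added after seeing the data. The sex of each mouse is not labelled. High Xist was found in 2 of the 4 control mice and 1 of the 4 conditional knockout mice. Control and conditional knockout mice share no litter or pairing label, so no paired fit between genotypes was made. Any pair of the 8 libraries correlated with r of 0.942 to 0.989 across the better-expressed genes of the SPN-like sums, and each library had its own total count, so all were kept as separate mice.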

Results

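The striatum of 8 mouse pups was profiled by single-nucleus RNA sequencing at postnatal day 8. The series compares 4 control mice (Dlx5/6-Cre) with 4 mice in which Zswim6, named by the submitters as a chromatin regulator of striatal circuit development, was targeted in striatal neurons (Dlx5/6-Cre with conditional Zswim6 alleles). The files gave raw UMI counts, with 21131716 UMIs in conditional knockout replicate 1, the fewest, and 53135404 in conditional knockout replicate 4, the most. Median depth per nucleus was 2659 ± 495 UMIs in controls and 3140 ± 976 in conditional knockouts (mean ± SD, n = 4 mice each; exact permutation p = 0.514). After filtering, 52670 nuclei remained, of which 28199 were SPN-like. SPNs are the GABAergic output neurons of the striatum: direct-pathway SPNs express the dopamine receptor gene Drd1, indirect-pathway SPNs express Drd2, and eccentric SPNs are a smaller class marked by genes such as Casz1 and Otof. Per mouse, 1532 to 2563 direct-pathway and 873 to 1888 indirect-pathway SPN-like nuclei were summed. The sequencing core's sample numbers place control replicate 1 and conditional knockout replicate 3 in 1 number series and the other 6 mice in another, called here the 2-mouse and 6-mouse series. The first principal component of the direct-pathway sums (42.8% of variance) was 14.66 and 11.32 in the 2-mouse series and -9.05 to -0.31 in the others, so values within the 6-mouse series (3 against 3) and the 2-mouse series (1 against 1) are given beside the pooled ones. The labels describe separate mice, and p-values of single genes and of values per mouse measure the spread between mice. Those of camera with the preset correlation set the genes of a list against the other genes tested, so they do not measure that spread alone.

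Zswim6 transcripts remained abundant in the conditional knockouts. Zswim6 (ENSMUSG00000032846) lies on the minus strand of chromosome 13 at 107724617 to 107890064 (GRCm38). In direct-pathway SPN-like nuclei its level was 8.65 ± 0.14 log2 CPM in controls and 8.47 ± 0.21 in conditional knockouts (SD, n = 4 each), a log2 fold change of -0.18 ± 0.11 (SE; edgeR adjusted p = 0.999). In indirect-pathway SPN-like nuclei it was 9.21 ± 0.13 against 8.99 ± 0.19, a log2 fold change of -0.23 ± 0.11 (edgeR adjusted p = 0.996). Among other classes of the GABAergic lineage, the log2 fold change was 0.33 ± 0.14 in eccentric SPN-like nuclei (edgeR adjusted p = 0.81), 0.26 ± 0.15 in neuroblast-like nuclei (0.999) and close to 0 in interneuron-like nuclei (-0.001 ± 0.13). In astrocyte-like nuclei it was 0.09 ± 0.15 and in oligodendrocyte precursor-like nuclei 0.05 ± 0.16, neither past the threshold. Individual direct-pathway values were 8.44, 8.69, 8.71 and 8.76 in control replicates 1 to 4 and 8.28, 8.51, 8.75 and 8.34 in conditional knockout replicates 1 to 4. Which exons Cre removes and whether introns were counted are not known here, and 3' tags from outside the deleted part do not report the deletion, so these counts do not check the labels.

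Relative to the 5 classes outside the Dlx5/6 lineage that were compared within each mouse, Zswim6 averaged over the direct-pathway and indirect-pathway classes (eccentric SPN-like nuclei left out) was higher by 0.68 ± 0.08 log2 units in controls and 0.44 ± 0.14 in conditional knockouts (SD, n = 4 each). The difference of -0.23 had an exact permutation p of 0.0286, the smallest that 4 mice against 4 can give, and no conditional knockout mouse overlapped a control mouse. Within the 6-mouse series, the log2 fold change was -0.34 ± 0.08 in direct-pathway nuclei (edgeR adjusted p = 0.145) and -0.38 ± 0.08 in indirect-pathway nuclei (0.0966), whereas in the 2-mouse series the conditional knockout mouse was higher by 0.30 and 0.23. The within-mouse difference was -0.30 in the 6-mouse series (exact permutation p = 0.1, the smallest possible for 3 against 3), where the 2-mouse series had 0.642 in the control and 0.587 in the conditional knockout. It was -0.22 with equal numbers of nuclei per mouse (0.0571) and -0.21 without nuclei of very high UMI counts (0.0857). Leaving out any 1 control mouse also gave 0.0571.

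**Figure D1:**
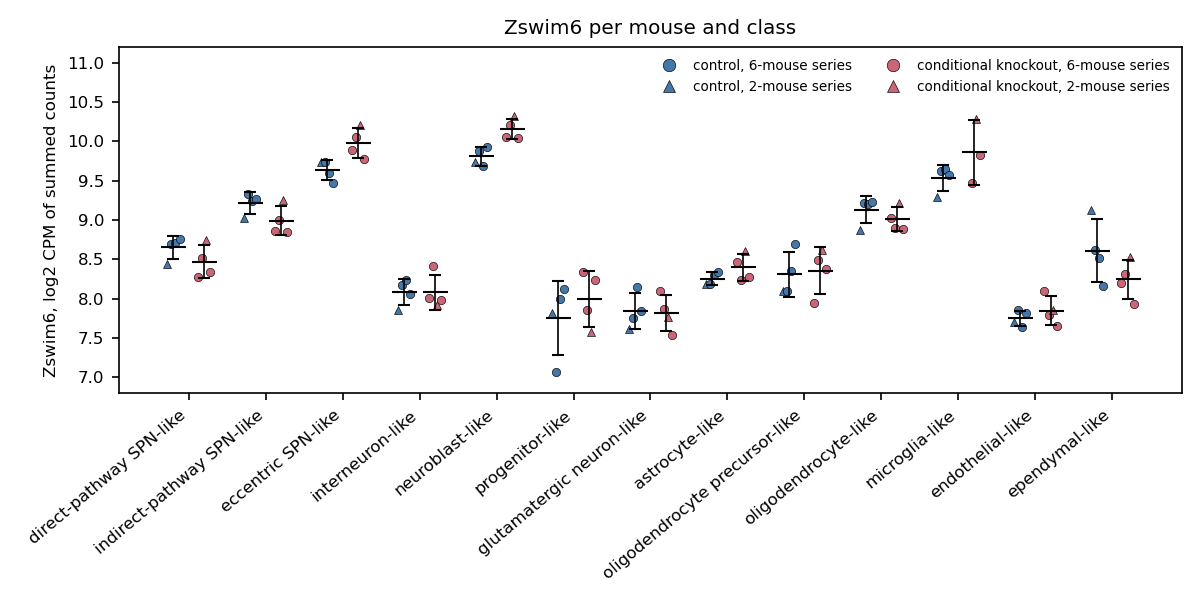
Zswim6 level in log2 CPM (vertical axis) for each mouse and cell class (horizontal axis), controls beside conditional knockouts, with the mean and SD of each group, marker shapes for the 2 core series, and mice with at least 20 nuclei of the class. Direct-pathway means were 8.65 and 8.47 and indirect-pathway means 9.21 and 8.99, with overlapping mice.

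Direct-pathway SPN-like nuclei differed between genotypes in 4 of 14552 genes tested (edgeR, adjusted p under 0.05), 2 higher and 2 lower in conditional knockouts. Otof (ENSMUSG00000062372, chromosome 5 at 30367062 to 30461932), which encodes otoferlin, a calcium sensor of synaptic vesicle release known from inner hair cells, rose from 4.42 ± 0.27 to 5.50 ± 0.18 log2 CPM (SD, n = 4 each; log2 fold change 1.08 ± 0.14 SE, edgeR adjusted p = 0.0229). Hjurp (ENSMUSG00000044783, chromosome 1 at 88262471 to 88277633), the chaperone that loads the centromeric histone CENP-A, fell from 4.03 ± 0.31 to 2.50 ± 0.42 (-1.53 ± 0.21, edgeR adjusted p = 0.0229). The other calls were outside the naming rule and were named after their values were seen. Zfp773, a zinc finger gene on chromosome 7 (7127073 to 7136755), rose from a low level of 0.12 ± 0.15 to 1.87 ± 0.30 (2.09 ± 0.32, edgeR adjusted p = 0.038), and AC149090.1, a protein-coding gene model on an unplaced scaffold, fell from 10.08 ± 0.72 to 8.42 ± 0.14 (-1.79 ± 0.26, edgeR adjusted p = 0.0229). Each of the 4 genes separated all control mice from all conditional knockout mice, as did 2.69% of all tested genes, against 2.86% by chance.

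The direct-pathway changes had the same sign in both core series, which follows from groups that do not overlap and is no separate support. Otof was higher by 1.00 in the 6-mouse series and by 1.36 in the 2-mouse series, Zfp773 by 2.15 and 1.45, while Hjurp changed by -1.42 and -1.81 and AC149090.1 by -2.0 and -0.79. Otof was also among the leading genes of 1 of the 3 direct-pathway clusters, so it was compared within each cluster after its value was seen. It was higher by 1.09, 1.16 and 1.85 log2 units in conditional knockouts in the 3 clusters (exact permutation p = 0.0286 each, the smallest possible). The clusters are parts of the sums in which Otof had been called, so these p-values are no separate evidence. The clusters' shares of the class were 45.3 ± 2.37, 37.1 ± 2.97 and 17.7 ± 1.72% in controls. In conditional knockouts they were 42.9 ± 5.63, 37.7 ± 4.38 and 19.5 ± 2.14% (SD; exact permutation p = 0.457, 0.83 and 0.286). At an unadjusted p under 0.05 edgeR listed 634 genes (322 higher, 312 lower), and DESeq2 called 11 genes and limma-voom 4. With the core series as a covariate edgeR called 2 higher and 9 lower genes, and in the 6-mouse series alone 3 higher and 32 lower. The 40 genes called lower in that series in either SPN-like class had a median log2 fold change of -0.36 in glutamatergic neuron-like and -0.46 in oligodendrocyte-like nuclei, outside the Cre lineage. It was -0.17 in oligodendrocyte precursor-like, -0.10 in endothelial-like and 0.03 in astrocyte-like nuclei. SPN RNA in the droplets of these classes was not separated from expression. Without conditional knockout replicate 2 or 4 or control replicate 4, 0 genes were called higher, and without control replicate 3 or 4 or conditional knockout replicate 1, 2 or 4, 0 were called lower. Among all 35 splits of the 8 mice into groups of 4, 5 gave at least 2 higher genes and 2 at least 2 lower genes, the real split included. The others of these placed both mice of the 2-mouse series in 1 group, and in most of them all mice with high Xist also shared a group. Sex genes were not left out of these counts. The 19 other splits that part the 2-mouse series, as the real one does, gave 0 calls.

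Indirect-pathway SPN-like nuclei also differed in 4 genes, of 13237 tested, with 1 higher and 3 lower in conditional knockouts. Adarb2 (ENSMUSG00000052551, chromosome 13 at 8202866 to 8768747), which encodes a brain RNA-binding protein of the ADAR family, rose from 5.48 ± 0.06 to 6.21 ± 0.18 log2 CPM (SD, n = 4 each; log2 fold change 0.75 ± 0.12 SE, edgeR adjusted p = 0.0357). Hjurp fell from 4.22 ± 0.29 to 2.74 ± 0.20 (-1.54 ± 0.20, edgeR adjusted p = 0.0118). Ero1lb (ENSMUSG00000057069, chromosome 13 at 12565874 to 12611396), an oxidoreductase of protein folding in the endoplasmic reticulum, fell from 4.02 ± 0.20 to 2.85 ± 0.29 (-1.22 ± 0.20, edgeR adjusted p = 0.0473). AC149090.1 fell from 10.01 ± 0.77 to 8.31 ± 0.11 (-1.85 ± 0.26, edgeR adjusted p = 0.0125). The groups of all 4 genes did not overlap, as in 2.79% of tested genes, against 2.86% by chance.

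Adarb2 was higher by 0.82 in the 6-mouse series and by 0.47 in the 2-mouse series, and by 0.89 and 0.56 within the 2 indirect-pathway clusters (exact permutation p = 0.0286 each, chosen after its value was seen). These clusters too are parts of the sums in which Adarb2 had been called, so the p-values are no separate evidence. Hjurp changed by -1.41 and -1.78, Ero1lb by -1.05 and -1.66, and AC149090.1 by -2.11 and -0.66 in the 6-mouse series and the 2-mouse series. At an unadjusted p under 0.05 edgeR listed 620 genes, and DESeq2 called 19 and limma-voom 2. With the core series as a covariate 12 genes were called higher and 21 lower, among them Cntn5 (-0.58 ± 0.08), Foxp2 (-0.59 ± 0.09), Spock1 (-0.64 ± 0.10) and Oprm1 (0.47 ± 0.09), named after their values were seen; in the 6-mouse series alone 4 were higher and 21 lower. The Adarb2 call was lost in 12 of 22 alternatives and that of Ero1lb in 15, including the omission of any 1 control mouse, while their signs held in all 22; the lower calls numbered 0 without control replicate 4 or conditional knockout replicate 1 or 2. Adarb2 and Ero1lb lie on chromosome 13, as Zswim6 does, and this chromosome held 9.95% of the 211 genes with an unadjusted p under 0.01 in either class, against 3.92% of the genes tested. Of the 35 splits, 7 gave at least 1 higher gene and 2 at least 3 lower genes, the real split included. Of the 19 others that part the 2-mouse series, 1 gave as many higher genes and 0 as many lower genes. That 1 split also placed all mice with high Xist in 1 group, and sex genes were not left out of the counts.

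**Figure D2:**
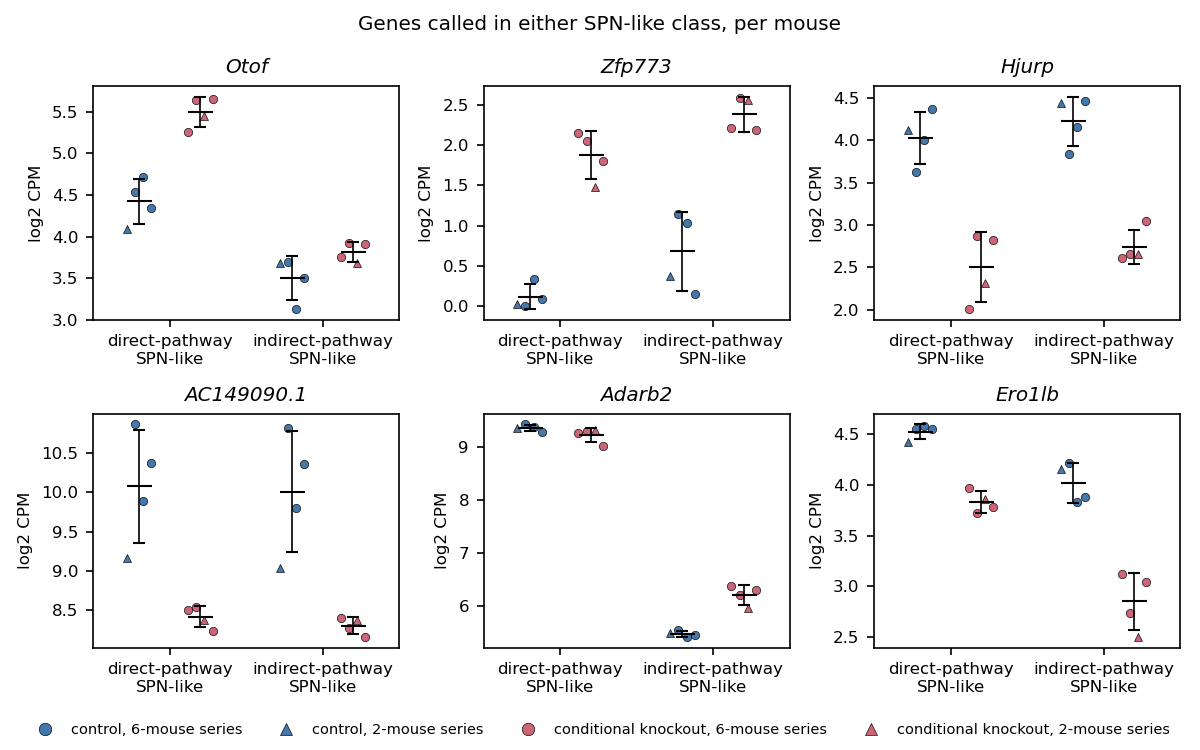
Level in log2 CPM (vertical axes) of each gene called in either SPN-like class, for each mouse by class and genotype, with the mean and SD of each group and marker shapes for the core series. Otof means rose from 4.42 to 5.50 in direct-pathway and Adarb2 means from 5.48 to 6.21 in indirect-pathway nuclei, with no overlap between genotypes in those classes.

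Among the fixed gene lists, 8 were lower in direct-pathway SPN-like nuclei of conditional knockouts (limma camera, preset correlation, adjusted p under 0.05). The mitochondrially encoded genes of the respiratory chain were lower in 12 of 13 members (median log2 fold change -0.23, adjusted p = 9.13e-06, or adjusted p = 0.797 with an estimated correlation), with 2 genes called when adjusted over the list alone, mt-Nd2 (-0.49 ± 0.13) and mt-Nd3 (-0.83 ± 0.23), and 0 over all genes. Receptors for glutamate of the NMDA, kainate, delta and metabotropic types were lower in 15 of 21 members (median -0.13, adjusted p = 0.00943, or 0.797 with an estimated correlation; 0 called adjusted over the list alone), with values of -0.30 ± 0.13 for Grin1, -0.24 ± 0.09 for Grin2b and -0.67 ± 0.23 for Grm8. Genes of indirect-pathway SPNs were lower in 11 of 12 members (median -0.28, adjusted p = 0.00943), with Drd2 at -0.45 ± 0.21 and Six3 at -0.37 ± 0.16, and all 6 tested indirect-pathway markers, which share members with that list, were below 0 (median -0.35, adjusted p = 0.0305). With an estimated correlation these lists had adjusted p = 0.797 and 0.864. In the 4 control mice Drd2 was at 3.27 to 3.61 log2 CPM in direct-pathway and 8.56 to 8.79 in indirect-pathway nuclei. Free RNA and misplaced nuclei were not separated from expression for these genes, and indirect-pathway nuclei themselves made up 21.6% of nuclei in controls and 18.7% in conditional knockouts. Lower lists also included mature SPN signalling (21 of 30 members, adjusted p = 0.0241), striatal developmental transcription factors (20 of 32, 0.0241), genes of the striatal matrix compartment (12 of 14, 0.0249) and markers of ependymal cells, which line the ventricle (7 of 9, 0.0256). With an estimated correlation the adjusted p of these 4 lists was 0.87, 0.797, 0.797 and 0.864. Free RNA was likewise not separated from expression for the ependymal markers, nor for the mitochondrially encoded genes, which are transcribed outside the nucleus, in either SPN-like class. Apart from the mitochondrial list, 0 members of these lists were called when adjusted over the list alone.

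Indirect-pathway SPN-like nuclei gave 9 changed lists. Mitochondrially encoded genes were lower in 12 of 13 members (median -0.22, adjusted p = 5.14e-06, or 0.538 with an estimated correlation; mt-Nd2 -0.45 ± 0.13 and mt-Nd3 -0.83 ± 0.22 called when adjusted over the list alone). Mature SPN signalling was lower in 23 of 30 members (median -0.09, adjusted p = 0.00116, or 0.738 with an estimated correlation; 0 called over the list alone), with Arpp19 at -0.38 ± 0.14 and Mef2c at -0.26 ± 0.10. Striatal developmental transcription factors were lower in 19 of 30 members (median -0.12, adjusted p = 0.00317, or 0.538 with an estimated correlation), with 3 called when adjusted over the list alone: Foxp2 (-0.60 ± 0.13), Six3 (-0.52 ± 0.14) and Zfhx4 (-0.52 ± 0.15). The NMDA, kainate, delta and metabotropic receptor list was lower in 15 of 20 members (adjusted p = 0.00351, or 0.563 with an estimated correlation), with Grm8 (-0.84 ± 0.20) called over the list alone. Matrix genes (12 of 14 lower, adjusted p = 0.018), markers shared by all SPNs (9 of 10 lower, 0.043) and ependymal markers (6 of 7 lower, 0.0251, with Tmem212 at -1.26 ± 0.30 called over the list alone) were lower. With an estimated correlation the adjusted p of these 3 lists was 0.563, 0.563 and 0.538. Immature neuron genes were higher in 20 of 27 members (median 0.08, adjusted p = 0.043; Dpysl3 0.29 ± 0.11), and cadherins and delta-protocadherins in 19 of 31 (median 0.09, adjusted p = 0.0475), with Cdh4 (0.54 ± 0.12) and Cdh20 (1.03 ± 0.21) called over the list alone. With an estimated correlation both had adjusted p = 0.738. Neuroblast markers, which share members with the immature neuron list, were above 0 in 7 of 9 without passing (camera adjusted p = 0.183). Neuroblast RNA and misplaced nuclei were not separated from expression for the immature neuron genes.

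None of these list calls held with an estimated correlation. With fry, 0 lists passed in either class, with lowest adjusted p of 0.822 and 0.563. In the 6-mouse series alone the mitochondrial list had adjusted p = 1.07e-06 and 2e-07 in the direct-pathway and indirect-pathway class, while the direct-pathway calls of indirect-pathway markers (0.135) and ependymal markers (0.417) and the indirect-pathway calls of ependymal markers (0.0637) and cadherins (0.954) did not pass. With the core series as a covariate, the direct-pathway call of indirect-pathway markers (0.0543) and the indirect-pathway call of cadherins (0.0802) did not pass. With Xist as a covariate, calls were lost for striatal developmental transcription factors (0.0714) and ependymal markers (0.0927) in direct-pathway nuclei, and for cadherins (0.0758) and ependymal markers (0.073) in indirect-pathway nuclei. That covariate also gained 2 direct-pathway calls, of eccentric SPN markers (0.0273, against 0.146 without it) and of mural or fibroblast markers (0.0475, against 0.17). The 2-mouse series has 1 mouse per genotype and gives no list test.

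Lists that did not pass camera in either class included AMPA receptor subunits (adjusted p = 0.792 in direct-pathway and 0.895 in indirect-pathway nuclei), GABA synthesis, transport and receptors (0.854 and 0.572), repressive chromatin complexes (0.54 and 0.572), BAF, MLL and histone acetylation complexes (0.64 and 0.382) and immediate early genes (0.822 and 0.908). High-confidence autism and intellectual disability genes did not pass over all mice (0.113 and 0.0835) but were lower with the core series as a covariate (0.0404 and 0.037) and in the 6-mouse series (0.00101 and 0.000477), all with the preset correlation. With an estimated correlation over all mice they had 0.895 and 0.878. Postsynaptic scaffolds and synaptic adhesion genes had 0.115 and 0.175 over all mice. They were also lower with the covariate (0.0228 and 0.037) and in the 6-mouse series (0.000312 and 0.000164), against 0.87 and 0.878 with an estimated correlation over all mice. The estimated correlation was not applied to the covariate and 6-mouse fits, and in the 6-mouse series fold change fell with gene length across genes, which are not independent replicates (Spearman rho = -0.116 and -0.106). In all, 7 direct-pathway and 3 indirect-pathway lists passed in the 6-mouse series and not over all mice. Striosome genes did not pass as a list (0.474 and 0.342), but in indirect-pathway nuclei the opioid receptor gene Oprm1 (0.47 ± 0.11) was called when adjusted over the list alone. From the list of dopamine, acetylcholine, serotonin, adenosine, opioid and cannabinoid receptors (adjusted p = 0.649), indirect-pathway nuclei gave 4 genes called when adjusted over the list alone: Drd3 (1.31 ± 0.33), Oprm1, Htr7 (-0.65 ± 0.20) and Oprk1 (-0.45 ± 0.14). None of these 4 was called over all genes. Of the cell type markers, direct-pathway nuclei gave Otof and Cacng5 (0.84 ± 0.26) from the eccentric SPN markers (6 of 9 above 0, adjusted p = 0.146), Ebf1 (-0.36 ± 0.11), Cdh4 (0.54 ± 0.15) and Tnr (-0.31 ± 0.10) when adjusted over the list alone. Indirect-pathway nuclei gave Adarb2 and Tshz1 (-0.44 ± 0.15) from the eccentric markers (5 of 9 above 0, adjusted p = 0.536), Synpr (0.39 ± 0.12) and Cdh4. From the fixed lists they also gave Arhgef28 (0.97 ± 0.28), Six3 and Ntng1 (-0.75 ± 0.16).

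The genotype effect differed between direct-pathway and indirect-pathway SPN-like nuclei in 39 of 14856 genes (edgeR interaction with the mouse as a block, adjusted p under 0.05). Relative to direct-pathway nuclei, 23 genes were higher and 16 lower in indirect-pathway nuclei of conditional knockouts. Adarb2 had the smallest p, with a difference in log2 fold change of 0.90 ± 0.09 (SE, n = 4 mice per genotype; edgeR adjusted p = 1.23e-10): it was 0.75 ± 0.12 in indirect-pathway nuclei and -0.14 ± 0.09 in direct-pathway nuclei, where its control level was 9.37 ± 0.06 log2 CPM. The cell adhesion gene Cntn5 (contactin 5) gave -0.31 ± 0.03 (edgeR adjusted p = 7.8e-10), being -0.57 ± 0.13 in indirect-pathway and -0.28 ± 0.12 in direct-pathway nuclei. Foxp2, a transcription factor of SPN development, gave -0.41 ± 0.06 (3.45e-05), and Rxfp1, a relaxin receptor gene, 0.74 ± 0.13 (0.000279), with -0.79 ± 0.18 in direct-pathway and -0.07 ± 0.14 in indirect-pathway nuclei. Positive differences were found for Etl4 (0.37 ± 0.05), the teneurin gene Tenm1 (0.30 ± 0.05), the cadherin gene Cdh18 (0.29 ± 0.04), the cGMP-dependent kinase gene Prkg1 (0.30 ± 0.05) and Lrp1b (0.19 ± 0.03).

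All 39 genes were also called with the core series as a covariate, 22 in the 6-mouse series alone and 15 by DESeq2, and 12 in all 8 fits that left out 1 mouse. In the 6-mouse series the difference was 1.02 for Adarb2 (edgeR adjusted p = 6.35e-11), -0.35 for Cntn5 (2.83e-09) and -0.23 for Foxp2, which lost its call there (0.118) and with DESeq2 (0.254). The 2-mouse series has 1 mouse per genotype and gave no test of the interaction. Only Adarb2 and Otof among the 39 were also called within a single class, Otof with an interaction of -0.80 ± 0.18 (edgeR adjusted p = 0.0227).

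**Figure D3:**
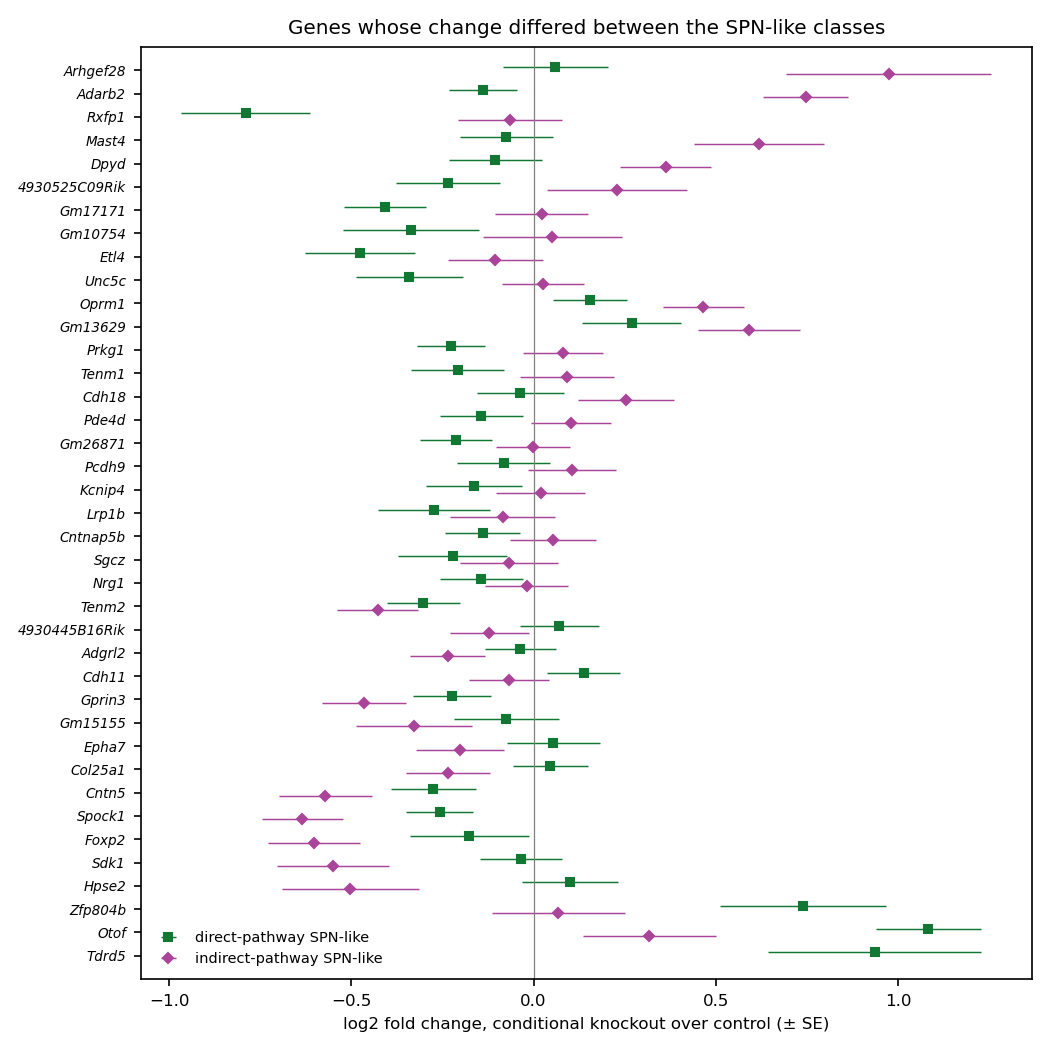
Log2 fold change of conditional knockout against control (with SE) in direct-pathway and indirect-pathway SPN-like nuclei, for the 39 genes whose change differed between the classes. Adarb2 was at -0.14 in direct-pathway and 0.75 in indirect-pathway nuclei, and Rxfp1 at -0.79 and -0.07.

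Across the 13196 genes tested in both classes, log2 fold changes correlated with Pearson r = 0.486 and Spearman rho = 0.459; genes are not independent replicates, and the classes share mice and droplet runs. Other splits of the 8 mice gave r of 0.328 to 0.704 (median 0.48). Hjurp and AC149090.1 were called in both classes, both lower, and 5 of the 35 splits, the real one included, gave at least 2 shared calls (highest other 15). In most of these other splits all mice with high Xist shared a group, and sex genes were counted.

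Outside the direct-pathway and indirect-pathway classes, 13 calls were made over 11 classes. AC149090.1 was lower in eccentric SPN-like (-1.79 ± 0.24), interneuron-like (-1.84 ± 0.25), neuroblast-like (-1.54 ± 0.23), glutamatergic neuron-like (-1.79 ± 0.23), astrocyte-like (-1.64 ± 0.22) and oligodendrocyte precursor-like nuclei (-1.83 ± 0.25; SE, n = 4 mice per genotype, highest edgeR adjusted p = 0.0099 among these). Hjurp was lower in interneuron-like (-1.67 ± 0.27, edgeR adjusted p = 0.0374) and glutamatergic neuron-like nuclei (-2.07 ± 0.33, 0.0137). Rora, a nuclear receptor gene, fell in glutamatergic neuron-like nuclei (-0.88 ± 0.15, 0.0171), Fstl5, a follistatin-like gene, in neuroblast-like nuclei (-1.25 ± 0.24, 0.0462) and Plcxd3 in eccentric SPN-like nuclei (-0.98 ± 0.17, 0.0145), and the remaining 2 calls, both in eccentric SPN-like nuclei, were gene models without a name. In progenitor-like, oligodendrocyte-like, microglia-like, endothelial-like and ependymal-like nuclei edgeR called 0 genes, with 99, 369, 10, 269 and 140 genes at an unadjusted p under 0.05, and DESeq2 called 0, 1, 0, 1 and 1 and limma-voom 0 in each. Over all 11 classes, 35 calls were made in the 6-mouse series alone and 82 with the core series as a covariate, with some genes called in several classes. Eccentric SPN-like nuclei held 43 of these 82 (15 higher, 28 lower), against 4 calls without the covariate. Among the covariate calls, the SPN genes Ebf1 (-1.34), Rarb (-0.71), Pde10a (-0.57) and Foxp1 (-0.49) were lower in glutamatergic neuron-like nuclei, beside Rora. In direct-pathway and indirect-pathway nuclei Rora was at -0.32 ± 0.10 and -0.38 ± 0.11. SPN RNA in the glutamatergic droplets was not separated from the expression of these genes. Rora, Fstl5 and the glutamatergic Hjurp call were lost in the 6-mouse series.

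The share of direct-pathway SPN-like nuclei was 30.1 ± 1.77% in controls and 30.01 ± 3.35% in conditional knockouts, and that of indirect-pathway SPN-like nuclei 21.6 ± 1.27% and 18.7 ± 3.6% (SD, n = 4 mice each; exact permutation p = 0.943 and 0.229). Neuroblast-like nuclei, which express Dcx and Sox11, made up 2.15 ± 0.401% and 4.58 ± 2.02% (exact permutation p = 0.0857), and 2.05% and 5.37% within the 6-mouse series (exact permutation p = 0.1, the smallest possible). In the 2-mouse series the difference had the other sign (-0.219 percentage points). The neuroblast-like clusters had 0.34 and 0.43 of the library median UMIs. Their SPN marker levels were 0.56 and 0.55 of those of SPN nuclei, just under the threshold of 0.6 for mixed nuclei. A larger cluster with neuroblast markers, at 0.88, was kept out as mixed. The effect of that threshold on these shares was not tested. With a smallest possible p of 0.0286, no single class could pass the adjustment over 13 classes (lowest adjusted p = 0.743). The ratio of direct-pathway to indirect-pathway nuclei was 1.39 ± 0.083 in controls and 1.63 ± 0.165 in conditional knockouts, a log2 difference of 0.22 (exact permutation p = 0.0857). It was 0.26 within the 6-mouse series (exact permutation p = 0.1, the smallest possible) and 0.10 in the 2-mouse series. When each mouse was left out in turn, it was largest without conditional knockout replicate 3, at 0.29 (exact permutation p = 0.0286, the smallest possible for 4 against 3). That omission keeps the control of the 2-mouse series, so the groups are then not balanced by series. Mixed nuclei were 15.9 ± 0.694% and 14.6 ± 1.76% (exact permutation p = 0.229), and unnamed nuclei 3.23 ± 0.888% and 5.48 ± 2.52% (exact permutation p = 0.0857). Few mice held most of 2 unnamed clusters. In 1 of them, 473 nuclei came from conditional knockout replicate 4 and at most 52 from any other mouse. The other had 118 and 234 in conditional knockout replicates 2 and 3 and at most 10 in any other mouse.

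**Figure D4:**
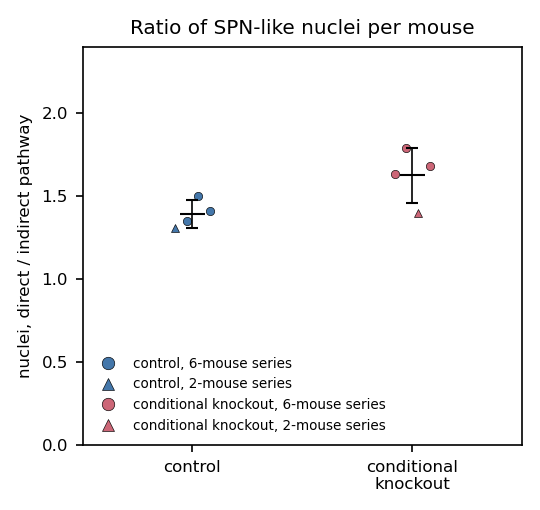
Ratio of direct-pathway to indirect-pathway SPN-like nuclei (vertical axis) in each mouse by genotype, with the mean and SD of each group and marker shapes for the core series. The means were 1.39 and 1.63, and conditional knockout replicate 3, from the 2-mouse series, lay at 1.40 among the controls.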

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

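The tests by splits of the mice, of SPN RNA in other droplets, of a variant in all cells, of a chromosome 13 segment, of a change shared outside the lineage and of class mixing were set only after the results were seen, while those of gene length, of UMI totals and of other SPN RNA behind Adarb2 were set before their own results were seen.

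Among 105 groups of mice tested, 3 had 1 mouse far from the others, against 5.2 by chance (1 in 20). Control replicate 4 had 1.75% glutamatergic neuron-like nuclei, the lowest of the controls. Control replicate 1 had a Zswim6 level of 8.87 log2 CPM in oligodendrocyte-like nuclei, below the other controls. Conditional knockout replicate 4 had a Hjurp level of 3.04 log2 CPM in indirect-pathway SPN-like nuclei, above the other conditional knockouts.

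The genotype effect in indirect-pathway minus that in direct-pathway SPN-like nuclei differed by edgeR's interaction test for 10 genes of smallest p: Adarb2 (0.90), Cntn5 (-0.31), Etl4 (0.37), the gene model Gm10754 (0.38), Tenm1 (0.30), Cdh18 (0.29), Foxp2 (-0.41), Prkg1 (0.30), Rxfp1 (0.74) and Lrp1b (0.19). Only 1 of the 35 splits of the 8 mice, the real one, gave as many as 39 genes, and the highest other split gave 7. The count thus stood out over the 35 splits, with the smallest share they can give. Of the 19 other splits that part the 2-mouse series, as the real one does, 0 gave as many. With the real one these are too few for a share under 0.05, so among them chance cannot be excluded. The called genes were long (median 566 kb, against 25.6 kb for genes tested), but a gene-length trend was too small to account for their differences. Its removal from each sum moved them by at most 0.033, against a smallest difference of 0.12 and a median of 0.31. After it, 35 of the 39 calls remained (Adarb2 0.88 ± 0.09). Why long genes prevailed was not tested. A change in how far the classes are mixed would push most genes one way, whereas 19 of the 39 moved towards the other class (48.7%, exact 95% limits 32.4 to 65.2). For Adarb2, direct-pathway RNA inside the indirect-pathway class would need a mean rise of 0.64 in 15 other direct-pathway genes, which changed by -0.13 ± 0.13. Eccentric SPN RNA cannot be told apart from a change in Adarb2 itself, because a share of only 1% would be enough and would raise 92 other eccentric genes by 0.14, against 0.009 ± 0.069 found. Adarb2 is itself 1 of the fixed eccentric markers, and of the others Tshz1 (-0.44 ± 0.15) and Casz1 (-0.36 ± 0.18) were lower in indirect-pathway nuclei while Otof (0.32 ± 0.18) was higher, so single markers speak on both sides. An effect of Zswim6 loss that differs between the SPN classes is a hypothesis that remains open.

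Hjurp and AC149090.1 were lower in conditional knockouts inside and outside the Cre lineage. SPN RNA in other droplets is argued against by control levels in glial classes at least 2.14 times (AC149090.1) those that SPN markers would give. For Hjurp, a segment of chromosome 13 around the targeted gene is argued against by its position on chromosome 1 (0 positions near Zswim6). For AC149090.1 such a segment cannot be told apart from other explanations, because its scaffold is unplaced (0 positions on an assembled chromosome). A variant carried by all cells of the conditional knockout mice may account for them: the median change outside the lineage was at least 0.78 of that in SPN-like nuclei (Hjurp -1.20 over 3 classes, AC149090.1 -1.7 over 6). Single classes outside it ranged from -2.07 to -0.59 for Hjurp and from -1.83 to -0.61 for AC149090.1. Of its 3 classes, Hjurp was called only in glutamatergic neuron-like nuclei, where SPN RNA was not compared. An effect of Zswim6 loss on these genes outside the lineage was not tested.

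More genes were lower in conditional knockouts once the 2-mouse series was left out, with 53 lower calls over both SPN-like classes (40 genes, median log2 fold change -0.51 ± 0.09). Unequal UMI totals are argued against, since 47 of 53 calls remained after thinning. Lower values were also found in classes outside the Cre lineage. In 2 of the 5 classes outside it that were tested, the genes fell by at least 0.5 times their SPN median. These were glutamatergic neuron-like (median -0.36, mean -0.47 ± 0.03 SE between mice) and oligodendrocyte-like nuclei (-0.46, mean -0.57 ± 0.20). In oligodendrocyte precursor-like nuclei the median was -0.17 (mean -0.37 ± 0.09), in endothelial-like -0.10 and in astrocyte-like 0.03 (mean -0.02 ± 0.09). SPN marker levels were 0.44 of those of SPN nuclei in oligodendrocyte-like nuclei and 0.28 and 0.25 in the glutamatergic neuron-like clusters. They were lower in astrocyte-like (0.24), endothelial-like (0.23) and oligodendrocyte precursor-like nuclei (0.18). A change shared with classes outside the lineage, or SPN RNA in their droplets, which was not tested for these genes, may thus be part of the pattern. A gene-length trend between libraries may be a source: after its removal 6 of 53 calls remained, with the median moving from -0.51 ± 0.09 to -0.40 ± 0.09. The genes had a median length of 494 kb against 25.9 kb for all genes tested. Across all genes, which are not independent replicates, fold change and length had Spearman rho of -0.116 and -0.106 in direct-pathway and indirect-pathway nuclei, and -0.205 in glutamatergic neuron-like and -0.299 in oligodendrocyte-like nuclei. The median fold thus shrank at the same error, but whether this alone ended the calls was not tested. The remaining change of -0.40 stays open, an effect of Zswim6 loss included. In the 2-mouse series the median of these changes was -0.09, with 36 of 53 below 0.

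For the other counts, chance cannot be excluded over the 35 splits. In direct-pathway SPN-like nuclei, 5 of the 35 splits gave as many higher genes as the real 2 (highest other 34) and 2 as many lower genes as the real 2 (highest other 32). In indirect-pathway SPN-like nuclei, 7 splits gave as many higher genes as the real 1 (highest other 25) and 2 as many lower genes as the real 3 (highest other 10). Over the other classes 9 splits reached the real 13 calls (highest other 379). The real 8 and 9 changed lists were reached by 18 and 12 splits (highest other 19 and 16), the 2 genes called in both classes by 5 (highest other 15) and the correlation of 0.486 by 18 (highest other 0.704). All 4 other splits with as many higher direct-pathway genes placed both mice of the 2-mouse series in 1 group, as did the other split with as many lower ones and the 8 others with as many calls in other classes. The core series may thus be a structure of the samples. Of the 15 splits that join these mice, however, only 4, 1 and 8 were as large in these counts. Sequencing depth was not separated from the series here, and neither was sex. Most of the 4 other splits with as many higher direct-pathway genes also placed all mice with high Xist in 1 group. Sex genes were not left out of the counts. The 19 other splits that part the 2-mouse series, as the real one does, gave 0 direct-pathway and 0 shared calls. They gave at most 7 calls in other classes, 2 higher and 2 lower indirect-pathway genes, and 13 and 10 lists. With the real one they are too few for a share under 0.05. With the core series as a covariate, the real split among these 20 gave 11 direct-pathway and 33 indirect-pathway calls, the highest others 4 and 3, and 1 split was as large in each class.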

How the results depend on the processing

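The settings that thinned UMIs, left out nuclei of very high UMI counts or joined the core series with Xist were chosen after seeing the data; all other settings were planned. Over all settings, 163 of the values that answer a comparison held and 90 counts moved by over 1.5 times, 7 tests lost and 1 gained the threshold; among single genes and lists 1304 held, 206 lost and 3 gained the threshold, 67 moved and 1 reversed. The cause of each change below was not tested, apart from fewer mice or fewer genes tested. With these depths and 4 mice per genotype, 31.2% of simulated 1.5-fold changes were recovered in direct-pathway nuclei; depth was not varied in the simulation. No paired analysis was possible because controls and conditional knockouts share no animal, litter or pairing label.

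In the 6-mouse series only, direct-pathway lower calls were 32, indirect-pathway 4 higher and 21 lower, class differences 24, other classes 35, shared calls 14 and direct-pathway lists 13, with Zswim6 within mice at -0.30 (exact permutation p = 0.1). With the core series covariate, direct-pathway lower calls were 9, indirect-pathway 12 higher and 21 lower, other classes 82 and shared calls 7. With the core series and Xist covariates, indirect-pathway calls were 6 higher and 12 lower and other classes 79. With the Xist covariate alone, higher calls were 1 in direct-pathway and 0 in indirect-pathway nuclei. With DESeq2, direct-pathway lower calls were 8, indirect-pathway 5 higher and 14 lower, class differences 15 and other classes 29. With limma-voom or with doublets kept, 0 indirect-pathway genes were higher. With no low-count filter, direct-pathway calls were 4 higher and 12 lower, indirect-pathway 22 higher and 34 lower, other classes 122 and shared calls 10. With UMIs thinned to the same total per mouse, direct-pathway calls were 1 higher and 1 lower, indirect-pathway 0 higher, class differences 25 and other classes 7. With equal nuclei per mouse, higher calls were 1 and 0 in the direct-pathway and indirect-pathway class and Zswim6 within mice was -0.22. With nuclei under 3 times the median UMI count, direct-pathway higher calls were 1 and Zswim6 within mice -0.21. With the estimated correlation and with fry, 0 lists passed in either class.

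Leaving out each mouse in turn gave 0 to 3 higher and 0 to 19 lower direct-pathway calls, 0 to 3 higher and 0 to 14 lower indirect-pathway calls, 19 to 42 class differences, 7 to 23 calls in other classes and 0 to 8 shared calls. Changed lists numbered 3 to 14 in direct-pathway and 2 to 13 in indirect-pathway nuclei, the log2 ratio difference was 0.17 to 0.29, and Zswim6 within mice was -0.28 to -0.16. The highest counts of lower calls came without conditional knockout replicate 3, of the 2-mouse series. Without that mouse the list of cadherins and delta-protocadherins, indirect-pathway SPN-like nuclei, turned to the other direction (adjusted p = 0.983), and over the omissions its adjusted p ranged from 0.000354 to 0.983.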

Other observations

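The tests of chromosome 13 and of eccentric SPN RNA behind Otof were chosen after the results were seen.

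Genes of chromosome 13, which holds Zswim6, were over-represented among genes changed in SPN-like nuclei. Of 211 genes with an unadjusted edgeR p under 0.01 in either class, 21 (9.95%) lay on chromosome 13, against 3.92% of the 13190 genes tested, the highest ratio of 20 chromosomes (next, chromosome 3 at 1.5). A cluster at 119488039 to 119790889 (GRCm38) held Tmem267 (-1.05 ± 0.19 in direct-pathway and -1.18 ± 0.23 in indirect-pathway nuclei), Nim1k (-0.71 ± 0.15 and -0.82 ± 0.16), Ccl28 (-0.79 ± 0.24 and -0.61 ± 0.26), Zfp131 (-0.31 ± 0.12 and -0.48 ± 0.12) and the gene model Gm41077 (-0.67 ± 0.18 and -0.55 ± 0.21), all lower in conditional knockouts. Near the other end, Tasor2 was at -0.54 ± 0.10 and -0.53 ± 0.13, beside Adarb2 and Ero1lb. Other members were higher, such as Gpr137b (0.66 ± 0.15 and 0.38 ± 0.19), and Arhgef28 (0.97 ± 0.28) and Mast4 (0.62 ± 0.18) in indirect-pathway nuclei.

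A candidate explanation is a segment of chromosome 13 carried with the targeted allele from another strain background. The share of chromosome 13 was 2.54 times its share of tested genes, and 1 of the 35 splits, the real one, was as large (highest other 2.08). Of the 21 genes, 8 lay within 20 Mb of Zswim6, 3.5 times their share (4 of the 35 splits as large), and 13 lay beyond it, 2.17 times their share (3 splits as large, highest other 2.28). Whether a segment within 20 Mb alone is the source thus cannot be told apart from a longer one, since neither part stands out from the splits. Adarb2 and Ero1lb, called in indirect-pathway nuclei, lie 99.3 and 95.2 Mb from Zswim6, out of reach of the shorter segment, and for a longer one they were not tested apart. The chromosome 13 genes were not compared in classes outside the Cre lineage, whose cells would carry such a segment too. The strain background of the mice is not given in the sources used here, and no reads were examined for variants.

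Otof, which rose in direct-pathway SPN-like nuclei, is a marker of eccentric SPNs. Eccentric nuclei or their RNA inside the direct-pathway class are argued against as the source: a share of 23.6% would be needed and would raise 114 other eccentric genes by 1.68 on average, and these changed by 0.052 ± 0.061 (SE between mice). Of the fixed eccentric markers, Cacng5 was also called higher in that class over its list alone. The list passed with Xist as a covariate (camera adjusted p = 0.0273) and not without it (0.146).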
